A study of Mus musculus with 20 samples.

How the data were processed

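The series holds 20 bisulfite libraries in 10 groups of 2: sperm, oocytes, and paternal and maternal pronuclei of WT or Tet3 CKO zygotes, mock or aphidicolin. Per the labels, libraries were typically made from about 20 pronuclei with 21 PCR cycles. Per the submitters' processing notes, Trim Galore and Bismark 0.10.1 were used with the mm9 build. The deposited files give, per CpG position, the count of methylated and of unmethylated calls, with no normalisation, and the deposited percent equals 100 times methylated over all calls in every row (largest difference 7.11e-14). The files have no header, and filters or removal of duplicates are not given in the sources used here. Bisulfite sequencing does not separate 5-methylcytosine from 5-hydroxymethylcytosine, so oxidation by Tet3 to the latter would not lower these values.

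Groups and replicate numbers came from the labels. Means were taken over the 68068 nuclear positions (autosomes and X) with at least 5 reads in all 20 libraries, each position weighted equally. Tiles of 100 bp needed at least 2 positions with 5 or more reads and at least 10 calls in each of the 10 libraries of a parent, which left 61904 paternal and 73688 maternal tiles. Gamete classes came from the gametes alone: at least 75% in 1 gamete and at most 25% in the other, at least 75% in both, or at most 25% in both. Mean differences were tested by exact two-sided permutation, stratified where several groups entered, with Benjamini-Hochberg adjustment over the 18 tests. An annotation of mm9 was not used here, the reference given being of another build, so the planned gene lists were not run and regions are named by position. Regions were called tiles of 1 direction less than 500 bp apart, at least 2 of them, in which both libraries of 1 group lay beyond both of the other, ranked by difference: the first 5 for the comparisons of WT mock with the gamete and of WT mock with WT aphidicolin and CKO mock, and the first 3 for the others.

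Each tile was tested with a quasi-binomial logistic model with 1 level per group, its overdispersion shrunk across tiles with limma 3.58.1 squeezeVar, an F test and Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 and a difference of at least 10 points. How the dispersion was shrunk was not settled before results were seen, and this departs from the design fixed beforehand. That design named a floor of 1 and shrinkage, which was run first, in that order and with all groups. In all, 13 specifications of the dispersion were run with their call counts in view, and the counts differed between them by over 10 times in several comparisons. The fit reported takes dispersion only from groups in which every library expects at least 5 calls of both kinds, trends it on depth, and applies the floor after shrinkage. It was kept for its behaviour on replicate number, for which no effect was assumed. It called 0 tiles on that number in each parent. Of tiles of 20% to 80% methylation, 3.93% of paternal and 3.50% of maternal ones had an unadjusted p under 0.05. Over all tiles these shares were 1.24% and 0.805%, so the test was conservative. The order of the fixed design called 1929 paternal and 10917 maternal tiles on replicate number. Other specifications held as well, with at most 1 such call where groups had to expect 5 or 10 calls, so that check does not single out the fit reported, and its counts are 1 choice among several. The test on replicate number was itself rebuilt once, after a first version took the tested deviance into the dispersion. The degrees of freedom of the replicate block were recounted after a first version gave no calls.

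The tile test and limma were tested on simulated counts drawn from the real depths and the dispersions of the fit reported. A tile had the same level in all groups, save for a rise in the CKO mock group at changed tiles. Changed tiles were taken from those of low methylation, and falls were not simulated. The stratified permutation test was tested on simulated normal values, where 4% of 200 draws without a shift gave a p under 0.05. Of 69 simulated paternal tiles changed by 60 points in the CKO mock against WT mock comparison the model called 31, and of 61704 unchanged tiles 0, in a step of 61904 tiles. For the same comparison in the maternal genome it called 17 of 63 and 0 of 73488, in a step of 73688 tiles. At 20, 40 and 60 points the model called 1.47%, 4.76% and 44.9% of changed paternal tiles and limma 16.2%, 23.8% and 44.9%; in maternal tiles the model called 0%, 8.62% and 27.0% and limma 10.1%, 17.2% and 39.7%. Of unchanged tiles limma called 0 paternal and 2 maternal. The median dispersion was 46.7 in paternal and 47.5 in maternal tiles, so that median tiles carried the information of about 6.14 and 4.91 independent calls per library. The mean dispersion of a group, over tiles with enough expected calls in that group, was 4.92 in sperm, 12.0 in oocytes and between 32.4 and 53.9 in pronuclei. One dispersion for all groups therefore understates the certainty of gamete values.

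Alternatives fixed before the data were examined were a minimum of 10 reads, positions weighted by reads, tiles as the unit, 1000-bp tiles, limma on log2 ratios of calls with 1 added to each, the replicate block, class limits of 90% and 10%, classes from 1 gamete replicate, and leaving out each library. The floor before shrinkage also came from the design fixed beforehand. The fit reported, the 11 other dispersion specifications, limma on arcsine square roots, the removal of both CKO libraries numbered 1, positions shared by the libraries of each parent, the model fitted to gamete and WT mock libraries only, and the block and library removals for gamete classes were added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.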

Results

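DNA methylation was measured by reduced representation bisulfite sequencing, which reads CpG-rich fragments cut by the enzyme MspI, in mouse gametes and in pronuclei isolated by hand from zygotes. A pronucleus is the nucleus that carries the genome of 1 parent before the first cleavage. Zygotes came from WT females or from females whose oocytes lacked Tet3 (CKO), the dioxygenase that oxidises 5-methylcytosine, and were fertilised with C57BL/6J sperm. They were cultured without (mock) or with 3 µg/ml aphidicolin, an inhibitor of DNA polymerases that blocks replication, from 5 hours after fertilisation, and pronuclei were taken at 12 hours. The 20 libraries formed 10 groups of 2: sperm, oocytes, and paternal and maternal pronuclei for each genotype and treatment. Libraries held between 22431861 and 68056783 CpG calls, and between 877632 and 1507589 positions with at least 5 reads. At the 68068 positions with at least 5 reads in all 20 libraries the median depth per library lay between 27 and 74 reads. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333, so differences are given with the range of the 4 differences between single libraries. Nothing in the labels says that libraries of a group came from separate animals, so the spread covers these libraries alone and may be technical. The labels also do not say whether paternal and maternal libraries came from the same zygotes. Tests over 4 strata, those of mitochondrial calls included, take them as independent. Their p would be too small if zygotes were shared.

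The first comparison asked how far each parental genome had moved from its gamete by the time of isolation. In the paternal genome, 100-bp tiles methylated in both gametes stood at 96.2% ± 0.0453 (SD, n = 2) in sperm and at 55.0% ± 2.87 (SD, n = 2) in WT mock pronuclei, over 3876 tiles. The 4 differences between libraries lay between -43.2 and -39.1 percentage points. Tiles methylated in sperm and not in oocytes, 4179 in number, went from 95.3% ± 0.0383 to 54.1% ± 3.05 (SD, n = 2 each). Tiles unmethylated in both gametes, 45654 in number, stood at 0.822% ± 0.000415 in sperm and 2.05% ± 0.407 in WT mock pronuclei (SD, n = 2 each). Mean methylation over all shared positions was 19.3% ± 0.0125 in sperm and 12.4% ± 1.03 in WT mock pronuclei (SD, n = 2 each), a difference of -6.94 points with an exact permutation p of 0.333. The difference was -3.14 points with positions weighted by reads and -4.41 with tiles as the unit.

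The maternal genome was compared with oocytes in the same way. Tiles methylated in both gametes stood at 96.2% ± 0.0253 in oocytes and 81.9% ± 1.97 in WT mock maternal pronuclei (SD, n = 2 each), over 6525 tiles, with the 4 differences between -15.7 and -12.9 points. Tiles methylated in oocytes and not in sperm, 1679 in number, went from 94.9% ± 0.165 to 82.6% ± 1.81 (SD, n = 2 each). Mean methylation over shared positions was 11.4% ± 0.0657 in oocytes and 9.44% ± 0.272 in WT mock maternal pronuclei (SD, n = 2 each), a difference of -1.96 points, or -3.00 with positions weighted by reads. The parental genomes were measured on different tile sets, and the difference between the parents was not tested. The WT mock files list their chromosomes in sorted order and the sperm and oocyte files do not, so a difference in preparation or processing cannot be separated from these changes from the gametes.

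**Figure D1:**
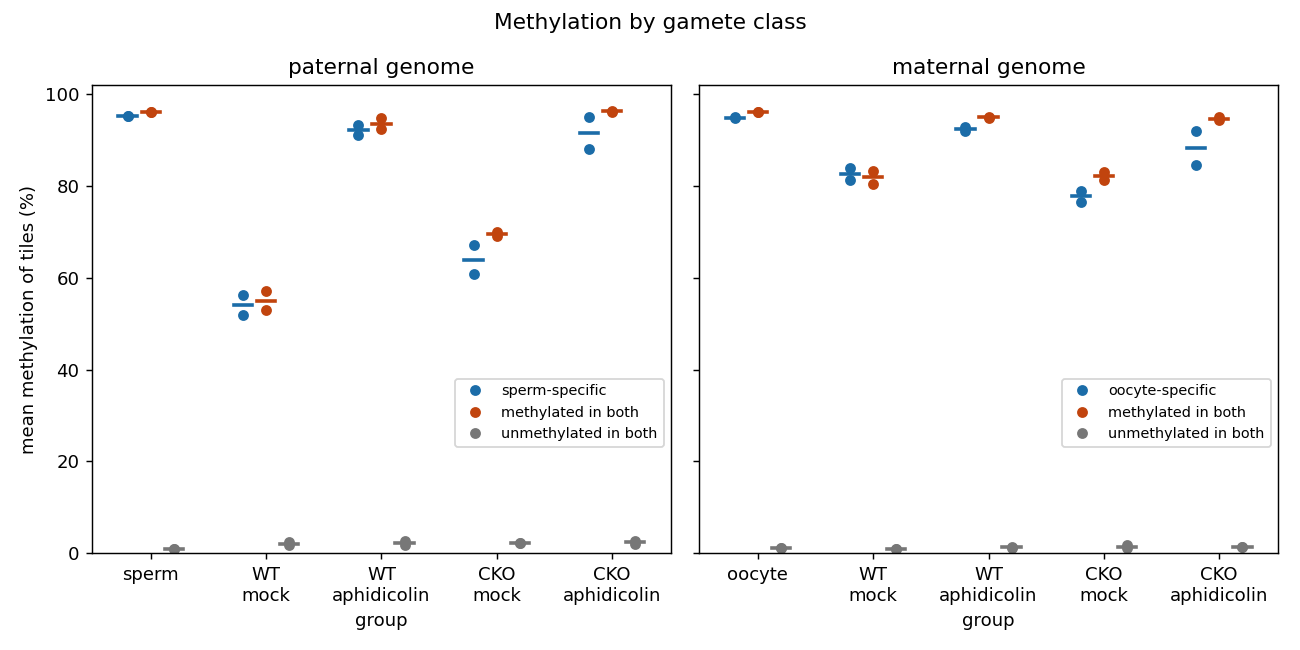
Mean methylation in percent (vertical axis) of tiles by gamete class, for the paternal genome (left) and the maternal genome (right), in the gamete and the 4 pronuclear groups (horizontal axis). Points are libraries and bars group means; tiles methylated in both gametes stood at 55.0% in WT paternal mock pronuclei and at 93.6% with aphidicolin, against 81.9% and 95.0% in the maternal genome.

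In the tile test, 966 of 61904 paternal tiles fell and 354 rose from sperm to WT mock pronuclei at an adjusted p under 0.05 and a change of at least 10 points. Among regions of joined tiles that fell, the largest change was at chromosome 11, 118752601 to 118752800 (mm9), at 96.2% ± 0.4 in sperm and 8.0% ± 11 in WT mock pronuclei (SD, n = 2 each, highest adjusted p = 0.020, 272 calls per tile). The next were at chromosome 1, 181509501 to 181509700, from 97.7% to 10.3%, and at chromosome 4, 132864601 to 132864800, from 97.0% to 11.1%. Regions at chromosome 19, 56591001 to 56591200, and at chromosome 5, 135515701 to 135515900, went from 95.3% to 9.8% and from 98.5% to 14.7%. None of the 5 regions kept a called tile without either sperm library. No annotation of mm9 was used here, so regions carry positions and no gene names. Fewer tiles were called in each direction whichever sperm or WT mock library was left out, and fewest without a sperm library. The differences of these 5 regions moved little without a sperm library, as at chromosome 11, at -88.0 and -88.6 points against -88.3. A lone sperm library was assumed to vary like the other groups, though the mean dispersion was 4.92 in sperm and 49.4 in WT mock pronuclei. The loss of calls thus does not show that the differences rest on 1 sperm library. With the dispersion floored before its shrinkage, the order fixed beforehand, the counts were 3026 lower and 601 higher. Over the 13 dispersion specifications they lay from 190 to 3026 and 105 to 937, and in 1000-bp tiles they were 9359 and 1188. Limma on log2 ratios called 0 tiles in every comparison, named regions included, and limma on arcsine square roots called 96 lower and 1 higher here. Fitted to the 4 sperm and WT mock libraries alone, the model called 0 tiles in either direction, with 5650 lower and 1531 higher at an unadjusted p under 0.05, so the calls rest on a dispersion shared with the other paternal pronuclei.

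The 354 tiles that rose stood at 1.03% in each sperm library and at 48.3% and 55.3% in the WT mock libraries. Regions of joined tiles lay at chromosome 17, 89191201 to 89191400 (78.0% ± 9.9 against 1.8% ± 0.4 in sperm, SD, n = 2 each, highest adjusted p = 0.015), chromosome 1, 15882501 to 15883100 (74.3% against 0.7%), and chromosome 13, 31707101 to 31707300 (72.9% against 0.4%, 966 calls per tile). They were followed by chromosome 9, 118398001 to 118398400 (66.8% against 0.4%) and chromosome 8, 95351501 to 95351700 (66.1% against 0.4%). Of these 5, only the regions on chromosomes 13 and 8 kept a called tile without either sperm library. The same 354 tiles stood between 36.1% and 49.9% in the 6 other paternal pronuclear libraries, which entered the dispersion of the call though not the difference tested. Of 495 tiles chosen by level alone, at most at 5% in both sperm and at least at 25% in both WT mock libraries (limits set after the values were seen), 243 were among the 354, and these 495 stood between 33.4% and 44.8% in the 6 other libraries. In the maternal genome, 14 of 73688 tiles fell and 1 rose from oocytes to WT mock pronuclei. The regions that fell were at chromosome 2, 112295101 to 112295400 (64.8% ± 1.05 in oocytes, 0.0371% ± 0.0525 in pronuclei, SD, n = 2 each) and at chromosome 11, 3093301 to 3093500 (65.4% to 44.4%), the latter at 20915 calls per tile against a median of 205. The chromosome 2 region kept no called tile without either oocyte library, and the chromosome 11 region none without oocyte replicate 1. In the chromosome 2 region libraries of 1 group stood far apart elsewhere, at 3.44% and 68.6% in WT aphidicolin, 21.9% and 0.0412% in CKO mock and 75.0% and 7.01% in CKO aphidicolin maternal pronuclei. In the chromosome 11 region these 6 libraries stood between 49.2% and 65.6%. The count that fell was 1 without either oocyte library, 6 and 5 without WT mock replicate 1 and 2, and 67 with the model fitted to oocyte and WT mock libraries alone, which called 15 higher. Over the 13 specifications it lay between 0 and 61, being 1 with the floor before shrinkage, and in 1000-bp tiles 159 fell and 38 rose. The tile that rose, named after its values were seen, was at chromosome 2, 127250901 to 127251000, with a change of 78.8 points.

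**Figure D2:**
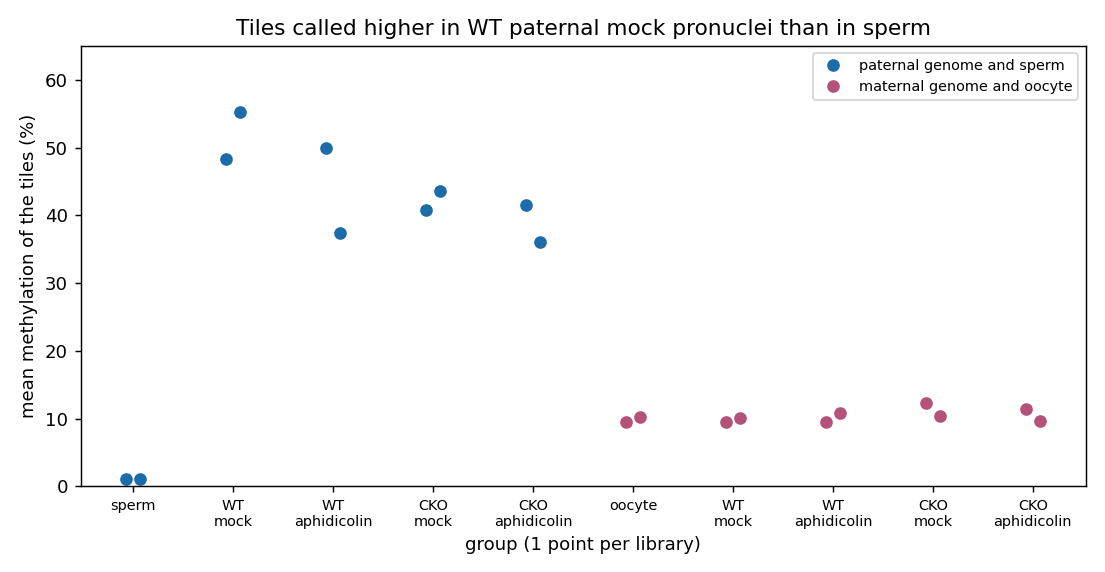
Mean methylation in percent (vertical axis) of the tiles called higher in WT paternal mock pronuclei than in sperm by group (horizontal axis), 1 point per library, over 354 tiles in sperm and paternal pronuclei and the 277 of them measured in oocytes and maternal pronuclei. Paternal pronuclear libraries lay between 36.1% and 55.3%, sperm at 1.03% and maternal libraries between 9.50% and 12.3%.

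The next comparison asked what aphidicolin, and so a block of replication, did to the change in WT zygotes. Paternal tiles methylated in both gametes stood at 93.6% ± 1.56 with aphidicolin and 55.0% ± 2.87 without (SD, n = 2 each), with the 4 differences between 35.5 and 41.7 points. Sperm-specific tiles stood at 92.2% ± 1.51 against 54.1% ± 3.05 (SD, n = 2 each). Maternal tiles methylated in both gametes stood at 95.0% ± 0.153 against 81.9% ± 1.97 (SD, n = 2 each), with differences between 11.6 and 14.6 points, and oocyte-specific tiles at 92.3% ± 0.604 against 82.6% ± 1.81. Mean methylation differed by 7.33 points in the paternal and 1.97 points in the maternal genome, the latter 0.681 points with positions weighted by reads. Over the 4 strata of parent and genotype, all 16 pronuclear libraries, mean methylation rose by 3.98 points with aphidicolin (exact stratified permutation test, two-sided, p = 0.00154, the smallest that 1296 arrangements can give; 0.0278 after Benjamini-Hochberg adjustment over 18 exact permutation tests of means). With replicate number as a block the exact permutation p was 0.00781, the smallest that the block allows, and 0.141 after the same adjustment. The test took paternal and maternal libraries as independent. If they came from the same zygotes, which the labels leave open, the p over 4 strata would be too small. Within the 2 paternal strata the difference was 6.49 points and within the 2 maternal strata 1.48 points. Each had an exact permutation p of 0.0556, the smallest that 36 arrangements can give. All mock pronuclear files and none of the aphidicolin files list their chromosomes in sorted order, so a difference in preparation or processing cannot be separated from the treatment.

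In the tile test 149 paternal tiles rose with aphidicolin and 1 fell. Regions that rose were at chromosome 8, 11239001 to 11239200 (19.7% ± 5.2 to 98.1% ± 0.7, SD, n = 2 each, highest adjusted p = 0.045), and at chromosome 5, 122319201 to 122319400 (16.7% ± 18 to 94.7% ± 7.2). The other 2 regions passing the rule lay on chromosome 17 at 39982501 to 39983100 (10.1% to 25.8%) and 39981701 to 39981900 (7.4% to 19.1%), at 39708 and 77679 calls per tile against a median of 259. Each of these 4 regions lost its called tiles without at least 1 of the 4 libraries compared, and without WT aphidicolin replicate 1 the differences on chromosome 17 were 10.1 and 7.63 points, against 15.7 and 11.8. The tile that fell, named after its values were seen, was at chromosome 18, 66813601 to 66813700, by 69.1 points. In the maternal genome 21 tiles rose and 1 was called lower, at chromosome 19, 6905601 to 6905700, also named after its values were seen, where the aphidicolin libraries stood at 13.7% and 99.0% and the mock libraries at 89.0% and 71.4%. The paternal rise was 2106 tiles with the dispersion floored before shrinkage, from 19 to 2106 over the 13 specifications, 5348 in 1000-bp tiles, where 88 fell, and 923 by limma on arcsine square roots. It was 45 and 259 without WT mock replicate 1 and 2, and 60 and 9 without WT aphidicolin replicate 1 and 2. The maternal rise was 275 tiles with that floor, from 0 to 275 over the specifications, 216 in 1000-bp tiles, 1 without WT mock replicate 1 and 6 without WT aphidicolin replicate 1.

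Loss of Tet3 was examined in mock zygotes. Paternal tiles methylated in both gametes stood at 69.5% ± 0.487 in CKO and 55.0% ± 2.87 in WT mock pronuclei (SD, n = 2 each), with the 4 differences between 12.1 and 16.9 points. In sperm the same tiles stood at 96.2%, so both genotypes lay below the gamete. Sperm-specific tiles stood at 64.0% ± 4.54 in CKO and 54.1% ± 3.05 in WT (SD, n = 2 each), with differences between 4.47 and 15.2 points. In the maternal genome, tiles methylated in both gametes stood at 82.2% ± 1.23 in CKO and 81.9% ± 1.97 in WT (SD, n = 2 each), a difference of 0.300 points that lay within the spread between libraries and was -0.573 and -1.09 without CKO mock replicate 2 and WT mock replicate 1. Maternal oocyte-specific tiles were at 77.7% ± 1.73 in CKO and 82.6% ± 1.81 in WT, while sperm-specific tiles in the same maternal libraries were at 9.81% ± 1.27 in CKO and 3.67% ± 0.224 in WT (SD, n = 2 each). Chromosome Y took 0.00297% and 0.000296% of calls in the CKO maternal mock libraries, 0.000692% and 0.000198% in the WT ones and at most 4.41e-05% in oocytes. Oocyte-specific tiles in the paternal libraries were at 8.28% ± 4.60 in CKO and 4.25% ± 0.923 in WT mock (SD, n = 2 each), with 11.5% in CKO replicate 1 and 5.02% in replicate 2. Over the 4 strata of parent and treatment mean methylation was 1.01 points higher in CKO than in WT (exact stratified permutation test, two-sided, p = 0.00309, adjusted 0.0278). It was 2.35 points with positions weighted by reads (adjusted exact permutation p = 0.0556) and 0.749 with tiles as the unit (adjusted exact permutation p = 0.0833). The adjusted exact permutation p was 0.0694, 0.0833 and 0.0556 without CKO paternal mock replicate 2, WT maternal mock replicate 1 and WT maternal mock replicate 2. It was 0.141 with replicate number as a block, so the call rests on these choices. The test also took the libraries of both parents as independent, which the labels do not show. Signal of the other parent in CKO libraries was not removed from these means, and its part in the difference was not tested. The difference was 1.36 points over the 2 paternal strata (exact permutation p = 0.0556, the smallest possible) and 0.657 points over the 2 maternal strata (exact permutation p = 0.111). Weighted by reads these were 3.70 and 0.999 points. The maternal one was 0.345 with tiles as the unit, 1.07 over positions shared by the maternal libraries and 0.410 without CKO mock replicate 2.

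At single tiles 18 rose and 1 fell in CKO paternal mock pronuclei against WT. Of the 18, 13 lay in 1 stretch of chromosome 17 and 14 had over 10 times the median depth, both limits set after the values were seen. The regions named there were 39981501 to 39983200 (8.3% ± 1.4 in WT, 23.6% ± 0.5 in CKO, SD, n = 2 each, highest adjusted p = 0.00048, 58775 calls per tile) and 39985201 to 39985700 (9.1% ± 1.2 to 21.8% ± 0.7). Sperm stood at 15.6% and 22.6% in the first of these. The other 4 tiles had lower depth. The count was 338 with the dispersion floored before shrinkage, where 108 fell, from 5 to 338 over the 13 specifications, 149 in 1000-bp tiles, where 22 fell, and 13, 6, 12 and 5 without WT mock replicate 1, WT mock replicate 2, CKO mock replicate 1 and CKO mock replicate 2. The tile that fell, named after its values were seen, was at chromosome 10, 79217801 to 79217900, with WT mock libraries at 81.5% and 26.2% and CKO mock libraries at 2.09% and 1.35%. In the maternal genome 1 tile rose, at chromosome 2, 152460301 to 152460400, and 2 fell, at chromosome 2, 149656801 to 149656900, and chromosome 17, 46633801 to 46633900, also named after their values were seen. These counts were 422 and 159 with the floor before shrinkage, 54 and 61 in 1000-bp tiles, 35 and 17 without both CKO libraries numbered 1, and 0 to 3 and 0 to 7 without 1 library. In simulated counts for this comparison the test called 44.9% of paternal tiles raised by 60 points and 4.76% of those raised by 40. Limma called 44.9% and 23.8%. Most rises of that size at tiles of low methylation would thus go uncalled, while falls and tiles of higher methylation were not simulated.

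Aphidicolin in CKO zygotes gave paternal tiles methylated in both gametes at 96.2% ± 0.0959 against 69.5% ± 0.487 in CKO mock (SD, n = 2 each), with differences between 26.3 and 27.1 points. The sperm level of the same tiles was 96.2% ± 0.0453. Sperm-specific tiles stood at 91.6% ± 4.94 against 64.0% ± 4.54 (SD, n = 2 each). They were at 88.1% in CKO aphidicolin replicate 1, where oocyte-specific tiles were at 11.05%, and at 95.1% in replicate 2, where these were at 5.39%. Maternal tiles methylated in both gametes stood at 94.6% ± 0.494 against 82.2% ± 1.23 (SD, n = 2 each). In the tile test 11 paternal tiles rose and 0 fell, with 3867 higher and 236 lower at an unadjusted p under 0.05, and limma called 0 in either direction. The count was 2219 higher and 162 lower with the dispersion floored before shrinkage and 5232 higher and 100 lower in 1000-bp tiles, and the rise was 2 without CKO mock replicate 1 and 3 without CKO aphidicolin replicate 1. The counts of 149 in WT and 11 in CKO do not by themselves show a difference between genotypes, which the interaction tests. In the maternal genome 11 rose and 2 fell, the latter at chromosome 7, 123291701 to 123291800, and chromosome 14, 102586901 to 102587000, named after their values were seen. These counts were 894 and 432 with the floor before shrinkage, 210 and 33 in 1000-bp tiles, and 2 to 16 and 0 to 2 without 1 library.

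With aphidicolin in both genotypes, CKO and WT paternal pronuclei stood at 96.2% ± 0.0959 and 93.6% ± 1.56 (SD, n = 2 each) at tiles methylated in both gametes, with differences between 1.47 and 3.81 points, and at 91.6% ± 4.94 and 92.2% ± 1.51 at sperm-specific tiles. The latter differed by -0.557 points, or 2.93 and -4.05 without CKO replicate 1 and 2. Maternal pronuclei stood at 94.6% ± 0.494 and 95.0% ± 0.153 at tiles methylated in both gametes, which differed by less than the spread between libraries. At oocyte-specific tiles they stood at 88.3% ± 5.15 in CKO and 92.3% ± 0.604 in WT (SD, n = 2 each). That difference was -4.02 points, with the 4 differences between -8.09 and 0.0463, or -0.381 and -7.67 without CKO replicate 1 and 2. Oocyte-specific tiles in the paternal libraries stood at 8.22% ± 4.00 in CKO and 4.89% ± 0.653 in WT, and sperm-specific tiles in the maternal libraries at 7.38% ± 2.73 and 5.08% ± 0.0872 (SD, n = 2 each). The quasi-binomial test called 0 paternal tiles in either direction, with 602 higher and 400 lower at an unadjusted p under 0.05, and limma called 0. In 1000-bp tiles 37 were called higher and 16 lower, other dispersion specifications called up to 4 higher and 2 lower, and 5 were higher without CKO aphidicolin replicate 2. The 100-bp test called 2 maternal tiles higher, at chromosome 6, 65331201 to 65331300, and chromosome 11, 83664901 to 83665000. It called 5 lower, starting at 41597101 on chromosome 8, 103815201 on chromosome 11, 36426301 on chromosome 15, 51952801 on chromosome 17 and 96412001 on chromosome X. These were named after their values were seen, and in the tiles on chromosomes 11, 15 and X that were lower 1 WT library stood at 0%. On chromosome 6 the CKO libraries stood at 95.1% and 12.5%, and on chromosome 17 the WT libraries at 26.7% and 99.7%. Libraries of a group lay closer together on chromosome 8 and in the chromosome 11 tile that was higher. The maternal counts were 0 and 0 with the floor before shrinkage, up to 30 and 59 under other specifications, 22 and 62 in 1000-bp tiles, and 0 to 3 and 2 to 12 without 1 library. Against sperm, CKO aphidicolin paternal pronuclei were higher at chromosome 2, 155340401 to 155340600 (84.3% ± 12 against 0.3% ± 0.1, SD, n = 2 each), chromosome 8, 25706201 to 25706400 (83.3% against 0.0%), and chromosome 2, 74565501 to 74565700 (78.4% against 0.1%). The 6 other paternal pronuclear libraries stood between 49.3% and 67.9%, 28.2% and 84.5%, and 40.9% and 75.8% in these regions, and the last 2 regions kept no called tile without either sperm library. The mean of CKO aphidicolin paternal pronuclei over shared positions was 20.2% against 19.3% in sperm, a difference of 0.904 points that was 5.99 with positions weighted by reads (25.3% against 19.3%). The aphidicolin effect in CKO minus that in WT was -1.67 points (SE 0.790) in the paternal and -0.978 points (SE 0.548) in the maternal genome; no exact test of this difference was run. The maternal value turned to 1.02 points with positions weighted by reads, and was -1.47 and -0.485 without CKO mock replicate 1 and 2. The paternal value was -0.947 and -2.40 without WT mock replicate 1 and 2. At single tiles the interaction passed in 2 paternal tiles, starting at 39981701 and 39985401 in the deep stretch of chromosome 17, and in 8 maternal tiles. These counts were 0 to 7 and 1 to 12 with 1 library left out, 0 to 33 and 0 to 47 over the 13 specifications, and 33 and 81 in 1000-bp tiles.

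Levels were also compared by CpG density, without a test. Among paternal tiles at or above 75% in sperm, those with 2 to 4 recorded CpG positions stood at 55.1% ± 3.59 in WT mock and 65.7% ± 2.27 in CKO mock pronuclei, and those with 10 or more at 57.5% ± 2.37 and 72.1% ± 0.790 (SD, n = 2 each). In the maternal genome, WT mock pronuclei stood at 79.1% ± 1.98 in tiles with 2 to 4 positions and 86.4% ± 1.71 in tiles with 10 or more. CKO mock pronuclei stood at 79.3% ± 1.75 and 81.8% ± 0.512 (SD, n = 2 each). In tiles with 5 to 9 positions, WT and CKO mock stood at 54.9% ± 2.34 and 68.0% ± 2.27 in the paternal genome. In the maternal genome they stood at 83.4% ± 2.00 and 82.8% ± 1.21 (SD, n = 2 each). Levels thus did not rise steadily with density in WT paternal and CKO maternal mock pronuclei. The 150 maternal X tiles stood at 76.2% ± 1.33 in WT mock against 82.0% ± 1.96 on autosomes (SD, n = 2 each). In CKO mock they stood at 78.0% ± 2.51 against 81.1% ± 1.34 (SD, n = 2 each). They were already lower in oocytes, at 93.0% ± 0.594 against 95.9% ± 0.0475 (SD, n = 2 each). The paternal X held 9 such tiles, and they are not compared here.

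Mitochondrial DNA took between 1.16% and 1.70% of calls in mock pronuclear libraries and between 2.60% and 4.19% with aphidicolin. Its methylation, a limit on incomplete conversion, lay at 0.155% (95% Wilson interval 0.146 to 0.164) in the lowest and 0.320% (0.306 to 0.335) in the highest pronuclear library. It separated by treatment, with all 8 aphidicolin libraries between 0.155% and 0.194% and all 8 mock libraries between 0.233% and 0.320% (exact stratified permutation test, two-sided, p = 0.00154, the smallest that 1296 arrangements can give, run after the values were seen). Mock files are sorted by chromosome and aphidicolin files are not, so treatment and processing cannot be told apart here. The oocyte libraries, unsorted and without aphidicolin, stood at 0.205% and 0.194%, below all mock libraries. Sperm libraries, also unsorted, stood above them at 15.2% and 1.16%, over 1159 and 1381 calls. Intervals cover counting error only, because PCR copies without molecular identifiers are not independent molecules.

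**Figure D3:**
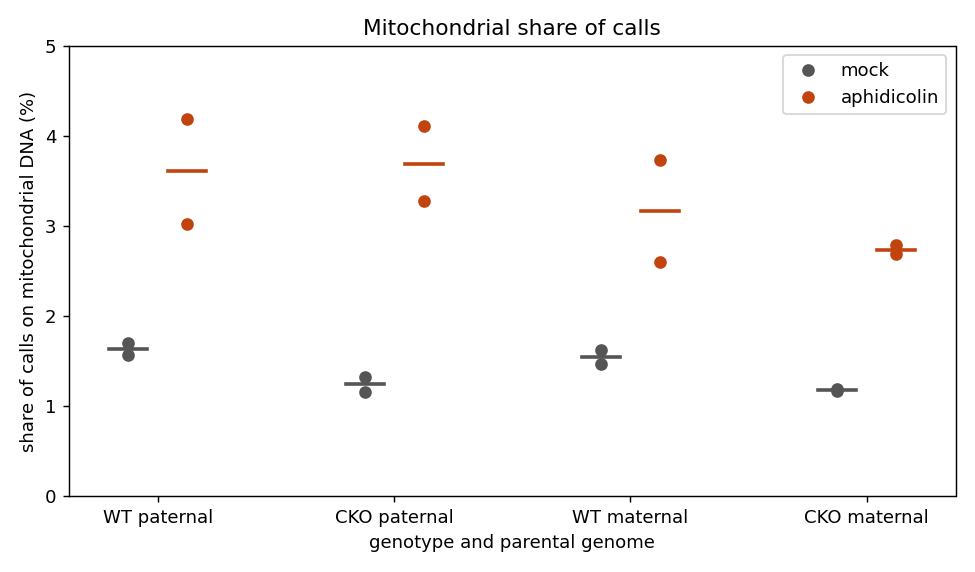
Share of CpG calls on mitochondrial DNA in percent (vertical axis) by parental genome and genotype (horizontal axis), 1 point per library with group means as bars. Mock libraries lay between 1.16% and 1.70% and aphidicolin libraries between 2.60% and 4.19%.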

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

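The tests of explanations in this part were chosen after their results had been seen, except the one on deep tiles. That test was written before its result, but its limit of 100 calls was set after values were seen. The interaction and its counts without 1 library were planned beforehand. The dispersion fit behind the counts given here was chosen after results were seen. In the order fixed beforehand, with the floor before shrinkage, 0 paternal and 2 maternal tiles passed. The interaction of genotype and aphidicolin passed in 2 paternal and 8 maternal tiles, and these counts rest on single libraries. The 2 paternal tiles lie in the deep stretch of chromosome 17. The paternal count was 0 without WT mock replicate 2, WT aphidicolin replicate 1 or either CKO mock library and 1 without WT mock replicate 1. It was 7, 6 and 5 without WT aphidicolin replicate 2, CKO aphidicolin replicate 1 and CKO aphidicolin replicate 2. The maternal count was 1, 3 and 12 without WT mock replicate 1, WT aphidicolin replicate 1 and CKO mock replicate 1, and lay between 0 and 47 over the 13 dispersion specifications. Libraries of 1 group stood apart in some of these tiles, as at chromosome X, 131076301 to 131076400, with 0% and 75.3% in WT aphidicolin. Mitochondrial calls in sperm replicate 1 were 15.2% methylated over 1159 calls, against 1.16% in sperm replicate 2.

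Chromosome Y, which a maternal genome lacks, took a higher share of calls in all 8 maternal pronuclear libraries than in oocytes, where it reached 4.41e-05%. In 6 of them the 95% Wilson interval lay above both oocyte intervals: 0.00297% and 0.000296% in CKO mock, 0.00163% in CKO aphidicolin replicate 1, 0.000692% and 0.000198% in WT mock, and 0.000508% in WT aphidicolin replicate 2. CKO aphidicolin replicate 2 was at 9.30e-05% and WT aphidicolin replicate 1 at 6.77e-05%. In the CKO mock libraries sperm-specific tiles stood 6.14 points above WT. Incomplete conversion is argued against, since tiles unmethylated in both gametes differed by 0.544 points. Paternal pronuclei among the maternal ones may account for the signal: sperm-specific tiles give paternal shares of 8.70% and 11.7%, which predict a change of -7.57 points at oocyte-specific tiles (-6.46 and -8.68 in the libraries), against -4.84 observed with differences between -7.34 and -2.33. The bound first set for this test was that range, and the prediction misses it. Paternal and maternal levels came from different tile sets, 4179 against 11745 sperm-specific and 2439 against 1679 oocyte-specific tiles. The CKO paternal mock libraries used as reference also held oocyte-specific tiles at 11.5% and 5.02%. Since the prediction of 1 library lies inside and Y gives shares of 22.8% and 2.27%, a part of paternal pronuclei is left open and not excluded. Loss of Tet3 raising maternal methylation also stays open, since tiles methylated in both gametes differed by 0.300 points with differences on both sides of 0, or 1.76 points, between -0.843 and 4.36, after removing the estimated share. That removal also combined different tile sets, 3876 paternal and 6525 maternal tiles.

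Mitochondrial DNA took 2.34 times the share of calls with aphidicolin as without (exact stratified permutation test, two-sided, p = 0.00154, the smallest that 1296 arrangements can give), and methylation was retained in the same libraries. Incomplete conversion is argued against, since tiles unmethylated in both gametes changed by at most 0.380 points and mitochondrial calls were less methylated with aphidicolin, at most 0.194% against at least 0.233%. Thin coverage stays open. The rise at tiles methylated in both gametes moved by at most 1.20 times in tiles with at least 100 calls in every library, a limit set after values were seen. It was smaller there in all 4 strata. In paternal WT and CKO it was 33.9 against 38.6 and 22.3 against 26.7 points. In maternal WT and CKO it was 11.2 against 13.1 and 10.6 against 12.4 points. Because PCR copies are not independent molecules, many calls do not show that a tile was well sampled, so this test cannot decide. A batch shared by the aphidicolin files cannot be told apart from the treatment, because 0 mock pronuclear files share their chromosome order, while the sperm and oocyte files are unsorted too. Unreplicated nuclear DNA may raise the mitochondrial share, but by at most 2 times, and the ratio was 2.04 to 2.97 over the 4 strata. Whether it is the only cause is open too, as the mean ratio did not pass a test against 2 (exact stratified permutation test, two-sided, p = 0.0617).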

How the results depend on the processing

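The fit reported, the 11 dispersion specifications other than it and the floor before shrinkage, the arcsine transform, the removal of CKO libraries numbered 1, positions shared by each parent, the fit to gamete and WT mock libraries only and the block and library removals of gamete classes were chosen after seeing the data; the other alternatives were not, and the floor before shrinkage was the order of the fixed design. Of 96 differences of gamete classes under other limits, classes or read minimums, 8 moved by over 1 SD. The block or leaving out 1 of 2 libraries cannot move them that far and says nothing of stability. The 8 were 27.3 (limits of 90% and 10%) and 26.1 (10 reads) for paternal CKO aphidicolin minus CKO mock and -0.0113 (10 reads) for paternal CKO aphidicolin minus sperm at tiles methylated in both gametes, -10.3 (limits of 90% and 10%) and -10.7 (class from replicate 1) for maternal WT mock minus oocyte and 7.77 (limits of 90% and 10%) for maternal WT aphidicolin minus WT mock at oocyte-specific tiles, and -0.729 and -0.771 (class from replicate 1 and 2) for maternal CKO aphidicolin minus oocyte at tiles methylated in both. Differences smaller than their SD changed sign under some settings, such as maternal CKO mock minus WT mock at tiles methylated in both (0.300 reported, -0.0670 with limits of 90% and 10%, -0.573 and -1.09 without CKO mock replicate 2 and WT mock replicate 1) and paternal CKO aphidicolin minus WT aphidicolin at sperm-specific tiles (-0.557 reported, 2.93 and 0.510 without CKO replicate 1 and WT replicate 2). Stratified tests of means kept their direction, and those over 4 strata an unadjusted exact permutation p under 0.05, while those over 2 strata cannot pass 0.05. CKO minus WT was 1.01 points over 4 strata as reported, 2.35 weighted by reads and 0.749 with tiles as the unit. Adjusted over 18 tests, the exact permutation p of aphidicolin over 4 strata was 0.0139 over positions shared by each parent, and from 0.0278 to 0.0417 without 1 library. That of CKO minus WT was 0.0139 over those positions, 0.0556 weighted by reads, 0.0833 with tiles as the unit, and from 0.0278 to 0.0833 without 1 library. The cause of these moves was not tested.

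Of 80 values of mean differences under other settings 26 moved by over 1 SD and 3 reversed. Stratified differences are among the 80 but were judged by direction and by p under 0.05, so they could not count as moved. Weighted by reads, paternal differences were -3.14 for WT mock minus sperm, 6.36 for WT aphidicolin minus WT mock, 4.63 for CKO mock minus WT mock, 4.50 for CKO aphidicolin minus CKO mock, 2.77 for CKO aphidicolin minus WT aphidicolin, 5.99 for CKO aphidicolin minus sperm. Maternal ones were -3.00 for WT mock minus oocyte, 0.681 for WT aphidicolin minus WT mock, 0.490 for CKO mock minus WT mock, 1.70 for CKO aphidicolin minus CKO mock, 1.51 for CKO aphidicolin minus WT aphidicolin, -0.815 for CKO aphidicolin minus oocyte, the last reversed, and 1.02 for the interaction, also reversed. With tiles as the unit, paternal differences were -4.41 for WT mock minus sperm, 5.15 for WT aphidicolin minus WT mock, 3.70 for CKO aphidicolin minus CKO mock, 0.430 for CKO aphidicolin minus WT aphidicolin, 1.17 for CKO aphidicolin minus sperm. Maternal ones were -1.56 for WT mock minus oocyte, 1.66 for WT aphidicolin minus WT mock, and -0.0350 for CKO aphidicolin minus WT aphidicolin, which reversed. Over positions shared by each parent, paternal CKO aphidicolin minus CKO mock was 5.15 and CKO aphidicolin minus sperm 1.01; with 10 reads the latter was 1.01. Maternal differences over shared positions were -2.56 for WT mock minus oocyte, 2.55 for WT aphidicolin minus WT mock, 1.69 for CKO mock minus WT mock, 0.442 for CKO aphidicolin minus WT aphidicolin, 0.433 for CKO aphidicolin minus oocyte. Without 1 library the interaction lay from -2.40 to -0.947 in the paternal and -1.47 to -0.485 in the maternal genome. The cause was not tested.

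Counts of called tiles depended on the dispersion and on single libraries, and no single count should be read alone. Of 392 counts under other settings 91 lay within 1.5 times of the count reported, 132 were lower and 169 higher. The lists that follow give tiles higher then lower for WT mock minus gamete, WT aphidicolin minus WT mock, CKO mock minus WT mock, CKO aphidicolin minus CKO mock and CKO aphidicolin minus WT aphidicolin, then tiles with interaction. As reported: paternal 354, 966, 149, 1, 18, 1, 11, 0, 0, 0, 2, maternal 1, 14, 21, 1, 1, 2, 11, 2, 2, 5, 8. With the dispersion floored before shrinkage: paternal 601, 3026, 2106, 108, 338, 108, 2219, 162, 0, 0, 0, maternal 0, 1, 275, 17, 422, 159, 894, 432, 0, 0, 2. With all groups and a trend on depth: paternal 208, 1521, 1000, 45, 151, 52, 988, 77, 0, 0, 0, maternal 0, 0, 0, 0, 157, 55, 325, 171, 0, 0, 0. With all groups and a trend on level: paternal 203, 1504, 873, 20, 28, 8, 788, 33, 0, 0, 0, maternal 0, 0, 3, 0, 0, 3, 146, 43, 0, 0, 0. With all groups and a trend on information: paternal 228, 1605, 883, 28, 24, 5, 764, 41, 0, 0, 0, maternal 0, 0, 0, 0, 0, 0, 0, 0, 0, 0, 0. With at least 1 expected calls and a trend on depth: paternal 937, 2799, 1386, 57, 51, 10, 906, 38, 0, 0, 0, maternal 17, 61, 160, 16, 33, 44, 121, 26, 30, 59, 47. With at least 1 expected calls and a trend on level: paternal 564, 2694, 1439, 10, 89, 7, 888, 8, 4, 2, 33, maternal 5, 29, 68, 6, 8, 12, 44, 9, 9, 17, 26. With at least 1 expected calls and a trend on information: paternal 628, 1879, 617, 10, 16, 3, 374, 3, 3, 2, 0, maternal 1, 19, 27, 0, 5, 3, 10, 3, 1, 6, 4. With at least 5 expected calls and a trend on level: paternal 478, 1486, 449, 4, 41, 3, 205, 2, 4, 1, 21, maternal 4, 24, 45, 2, 4, 8, 26, 6, 4, 13, 22. With at least 5 expected calls and a trend on information: paternal 442, 987, 178, 3, 5, 1, 64, 1, 1, 0, 0, maternal 1, 13, 20, 0, 3, 3, 9, 3, 1, 2, 4. With at least 10 expected calls and a trend on depth: paternal 105, 190, 19, 0, 11, 0, 1, 0, 0, 0, 2, maternal 1, 9, 4, 0, 1, 2, 7, 0, 0, 0, 1. With at least 10 expected calls and a trend on level: paternal 421, 868, 158, 2, 33, 2, 60, 1, 1, 1, 21, maternal 3, 20, 37, 2, 2, 6, 24, 5, 4, 12, 16. With at least 10 expected calls and a trend on information: paternal 300, 574, 62, 0, 11, 1, 16, 0, 0, 0, 0, maternal 1, 11, 13, 0, 1, 2, 10, 0, 0, 0, 1. By limma on arcsine square roots: paternal 1, 96, 923, 24, 0, 0, 0, 0, 0, 0, 0, maternal 0, 0, 0, 0, 0, 0, 0, 0, 0, 0, 0. With 10 reads per position: paternal 322, 823, 128, 1, 17, 1, 4, 0, 0, 0, 4, maternal 1, 14, 21, 1, 1, 2, 9, 3, 2, 4, 2. In 1000-bp tiles: paternal 1188, 9359, 5348, 88, 149, 22, 5232, 100, 37, 16, 33, maternal 38, 159, 216, 22, 54, 61, 210, 33, 22, 62, 81. Without both CKO libraries numbered 1, from CKO mock minus WT mock on: paternal 19, 1, 1, 1, 0, 0, 2, maternal 35, 17, 21, 3, 18, 10, 21. With gamete and WT mock libraries only, for WT mock minus gamete: paternal 0, 0, maternal 15, 67. Limma on log2 ratios called 0 tiles in all 22 counts, with between 414 and 6403 tiles at an unadjusted p under 0.05 in each, and so 0 of the 21 named regions. Leaving out 1 library gave, in the same order, paternal 11 to 336, 8 to 864, 9 to 259, 0 to 7, 5 to 13, 0 to 3, 2 to 9, 0 to 0, 0 to 5, 0 to 0, 0 to 7, and maternal 0 to 2, 1 to 6, 1 to 20, 0 to 3, 0 to 3, 0 to 7, 2 to 16, 0 to 2, 0 to 3, 2 to 12, 1 to 12. The cause was not tested, but a lone library is assumed to vary like the other groups.

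The replicate block gave paternal 133, 249, 10, 0, 8, 0, 3, 0, 0, 0, 0 and maternal 1, 9, 2, 0, 1, 2, 1, 0, 0, 0, 1 tiles, and 7 of the 21 named regions lost their calls. With the block the exact permutation p over 4 strata was 0.00781 for aphidicolin, the smallest that 256 arrangements can give, and 0.0156 for CKO minus WT, each 0.141 after adjustment over 18 tests. Whether replicate numbers pair the samples stays open. Within a parent, deviations of libraries with the same number had a mean correlation across tiles of 0.00814 (-0.0286 to 0.0443) in the paternal genome. In the maternal genome it was -0.00324 (-0.0237 to 0.00932), over 10 pairs of groups each. Libraries of different parents were not compared. In CKO paternal libraries oocyte-specific tiles were at 11.5% (mock) and 11.05% (aphidicolin) in replicate 1 and at 5.02% and 5.39% in replicate 2. Chromosome Y in CKO maternal libraries was also higher in replicate 1. Sperm-specific tiles there did not follow the number, at 8.92% and 9.31% in replicate 1 and 10.7% and 5.45% in replicate 2. Named regions kept at least 1 called tile in all 21 cases with 10 reads, and lost it in 35 of 84 cases with 1 library left out, 20 of them without a sperm library. A median tile of 259 paternal calls carried the information of about 6.14 independent calls. Whether PCR copies or other spread between libraries caused this was not tested. Gene lists were not run.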

Other observations

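The tests of the pattern below were chosen after its values had been seen. The 354 tiles that rose from sperm to WT paternal mock pronuclei lay on 20 chromosomes, and 95.8% held at least 5 CpG positions, against 90.1% of other tiles as low in sperm, a difference that was not tested. Incomplete conversion is argued against, since tiles unmethylated in both gametes reached at most 2.73% in a paternal library. Selection of tiles that were high by chance stays open for the 354 as called, because the 6 other paternal libraries helped to set their dispersion and the model fitted without them called 0 tiles, so that its part of the test is void. It is argued against for the 495 tiles chosen by level from sperm and WT mock libraries alone, 243 of them among the 354, which lay at least 32.3 points above other tiles as low in sperm in each of those 6. Maternal DNA is argued against for the 342 of the 495 also measured in the maternal libraries, taken as a set. Their mean reached at most 12.3% in an oocyte or maternal pronuclear library. Single tiles, and tiles of the 495 not measured there, are not covered. As a hypothesis, the paternal genome may gain methylation at the 495 after fertilisation: they averaged 38.0% in those 6 libraries, while DNA of other cell types was not tested.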
